A study of Drosophila melanogaster with 8 samples.

How the data were processed

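Gene expression was measured in 8 pools of fly heads, 4 per group, on 1-colour Agilent arrays with Cy3-labelled cRNA made from 0.4 ug of RNA per sample, per the labels' protocols. Samples were grouped by their titles, and the labels call the 4 samples of a condition independent. The scanner files hold spot intensity values, which the authors obtained with Agilent Feature Extraction 10.7.3.1 per the file headers, while the submitters' processing notes name version 9.1.3.1. That software subtracts background and detrends each array, per the file headers, and the array design's genome build is dm3 there. The authors' deposited value table is on the log2 scale. Set against the scanner values, it matched the log2 processed signal, with replicate spots averaged, scaled by each array's 75th percentile and with each probe's median over the 8 arrays subtracted. The correlation with the scanner deviations over probes ran from 0.991 to 0.994 on the 8 arrays, and the column medians from −0.0621 to 0.0378. The steps behind that table are not given in the sources used here, but its scale, centring and direction followed from this match.

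Spots with an outlier flag (1108 of the non-control spots over all arrays) and control spots were left out. The log2 of the processed signal, averaged over a probe's spots, was scaled by subtracting each array's 75th percentile, which lay between 4602 and 5356 intensity units. All levels are given on this log2 scale. A probe was kept when it was well above background on all 4 arrays of at least 1 group (22450 of 32162 probes) and its value was measured on at least 6 arrays. A gene or target with several probes took the probe with the highest mean.

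The scanner files name each probe's target by a transcript, clone or consensus identifier. Names were taken only from a RefSeq gene table of assembly Release 6 plus ISO1 MT, used for names and for which genes neighbour or overlap, with no coordinates since the builds differ. It paired 418 probes with 1 gene, 2 probes with several and 31742 with none. The 353 genes came from 215 matches of RefSeq accessions, 134 of cDNA clone names and 8 of FlyBase transcripts, with some found by more than 1 route. Of the 20130 probes for FlyBase transcripts 11 were named, so other probes of a named gene can lie among the unnamed targets. Of 43 tested genes with several probes, 6 had a probe that differed in sign from the probe used. The table gives no strand. The planned check of the elav and TrpA1 probes could not be read, since no probe could be named for either gene.

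The groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and plain eBayes with group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 17916 units tested and a threshold of 0.05. SE is the moderated standard error of the log2 difference, activated_31C minus control_23C. The list test was camera with a correlation of 0.01, for lists with at least 3 measured members. Genes named in the text were chosen by a rule written before the data were examined. It took the 12 largest positive and 12 largest negative differences past the threshold among genes with a symbol whose groups did not overlap. It also took up to 3 members of each fixed list with the smallest adjusted p, or the member with the largest difference where none passed. Genes it always names (TrpA1, elav, Hr38, sr, kay, Jra, Hsp70Aa, Hsp70Bb, Hsp83, Hsp26, per and tim) had no named probe. lncRNA:roX1, slo, sta, RpL7 and RpL29 are given as the other measured members of their lists, and the 4 unnamed targets as the largest rises and falls among those without a symbol.

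A gene or target none of whose probes was well above background on any array of a group has only a bound there. Its fold is then given as "at least", from the mean of the brighter group against the mean, over the dim group's arrays, of the higher of its own signal and the lowest signal well above background on that array. Of the 908 units changed at least 2-fold, 81 were below background on every array of a group. No spot was saturated on an activated_31C array, and between 5 and 15 were on a control_23C array. No pair of arrays held identical values.

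The steps were tested on simulated data made from the means and spreads of the 17916 units, with 200 changed by a known fold in a simulated comparison of activated_31C with control_23C. Of 67 units changed 1.5-fold, 71.6% were called, of 67 changed 2-fold 86.6%, and of 66 changed 4-fold 100%, with 6 false calls among the rest. The changed units were drawn from all but the noisiest, and the noise was independent and normal with no slide or array effect. Far fewer units were changed than were called in the real comparison, so these rates do not carry over to it directly.

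The alternatives tried were normexp background correction (offset 50), quantile normalization, centring on the median of probes well above background, centring on spike-in controls, the authors' table, no filter and a stricter filter, the mean over a gene's probes, outlier spots kept, trended robust variance, array weights, the replicate number as a block and leaving out each array. Normexp used the median spot signal in place of the mean signal named for it beforehand. Its offset of 50, added to every spot, by itself shrinks the log2 differences of dim targets. Leaving out control_23C replicates 3 and 4, and these with activated_31C replicate 3, was added after the arrays were seen. Plots were drawn with matplotlib 3.10.9.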

Results

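RNA was measured in adult heads of Drosophila melanogaster that carried the elav-GAL4 driver, which is active in neurons, and a UAS transgene of dTrpA1, a cation channel that opens with warmth. In such animals, warming depolarises neurons across the nervous system, and the study asked which transcripts in the head respond to that activity. Each of 8 samples was a pool of 20 heads of males and females. The 4 control_23C samples were kept at 23 °C, and the 4 activated_31C samples were moved to 31 °C for 1 h and dissected directly afterwards. Each sample was hybridised to its own 1-colour array. Between 22003 and 24402 of 32162 probes were well above background on a control_23C array, and between 22850 and 23769 on an activated_31C array. The precision of every value is limited by 4 arrays per group. All 4 control_23C arrays lay on 1 slide and all 4 activated_31C arrays on another, so slide and group cannot be told apart. Both groups had the channel, so the effect of warmth alone cannot be told apart from that of neural activity.

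The comparison of activated_31C with control_23C asked which transcripts changed within 1 h of warming. The gene with the largest rise among those with a symbol was lncRNA:alphagamma-element:CR32865, a long non-coding RNA that lies between Hsp70Ba and Hsp70Bbb in the Release 6 gene table. Its log2 signal was 4.16 higher in activated_31C (SE 0.0847, limma adjusted p = 2.51e-07, n = 4 per group), a 17.8-fold difference. CG7130, from the list of heat-inducible genes and their co-chaperones, rose by 3.42 on the log2 scale (SE 0.0932, adjusted p = 4.77e-07). The transcription coactivator gene mbf1 rose by 1.68 (SE 0.0448), and Pdk, which encodes pyruvate dehydrogenase kinase, rose by 1.44 (SE 0.0731). Falls among genes with a symbol were smaller, and the largest was that of lncRNA:CR33948, at −1.94 (SE 0.187, adjusted p = 0.000129).

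Over all 17916 genes and targets tested, 3494 were higher and 4453 were lower in activated_31C at an adjusted p under 0.05. The larger changes were mostly rises. At least 2-fold, 750 targets were higher and 158 lower, and at least 4-fold, 242 were higher and 12 lower. The median absolute change among the targets past the threshold was 0.41 on the log2 scale. In 43.9% of the targets tested, all arrays of a group lay outside the range of the other group, against 2.86% that chance gives with 4 against 4. A unit tested here is a gene where a symbol was found and otherwise the array's target, so several transcripts of a gene can be counted separately. Of the changed targets, 44.0% were higher, against 33.8% after quantile normalization and 22.8% after centring on spike-in controls, which lowered the count of higher targets to 1218. Centring on the median of probes well above background turned the majority, with 51.9% higher. The count of at least 2-fold changes was 908, and 527 with normexp background correction. With control_23C replicates 3 and 4 and activated_31C replicate 3 left out, on which a set of targets read far lower, 2203 targets were higher, 2283 lower and 902 changed at least 2-fold.

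**Figure D1:**
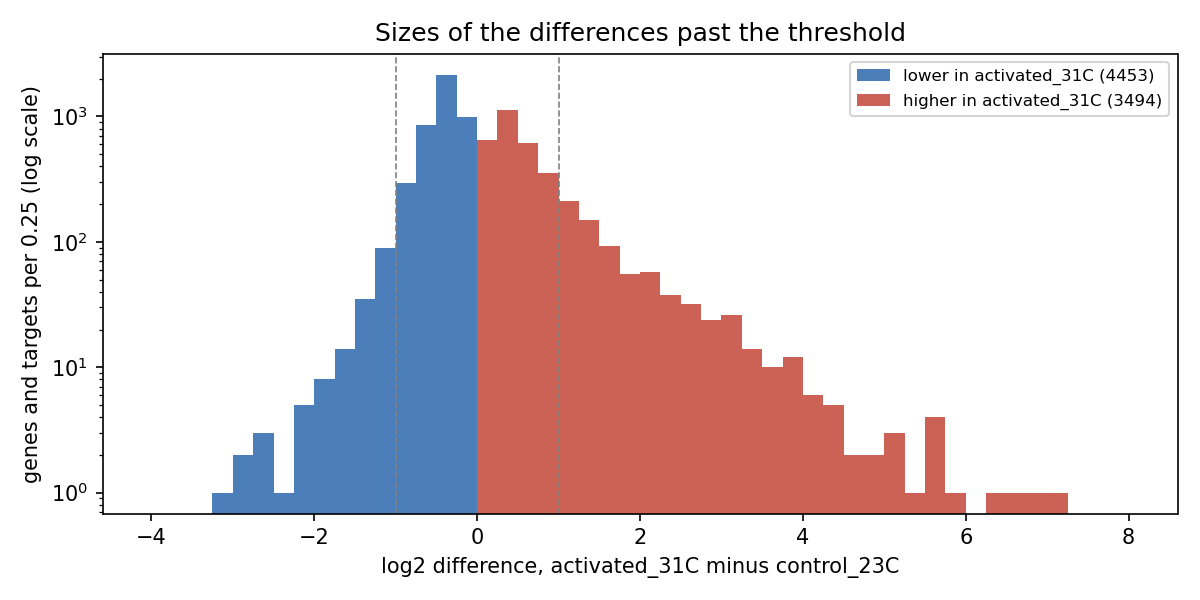
Number of genes and targets past the threshold (log scale) by their log2 difference, activated_31C minus control_23C, in steps of 0.25. The 3494 higher targets are in red and the 4453 lower ones in blue, dashed lines mark a 2-fold difference, and the rises reach further from 0 than the falls.

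Most targets had no gene symbol in the tables used here, and 260 genes with a symbol could be tested. Of these 53 were higher, 61 were lower and 146 did not pass the threshold. The largest rise of all was that of the transcript FBtr0082638, with a log2 signal of −1.02 ± 0.70 (SD, n = 4) in control_23C and 6.04 ± 0.06 in activated_31C. The transcript FBtr0082636 rose by 6.94 on the log2 scale (SE 0.355), from a mean of −0.937 in control_23C to 6.01 in activated_31C. Its levels were close to those of FBtr0082638 on each array, so the 2 may not be separate rises. The consensus target TC217326 was well above background on 4 control_23C arrays and on 0 activated_31C arrays, and was at least 3.71-fold lower in activated_31C (adjusted p = 4.77e-06). The target BT100245 fell by 2.84 on the log2 scale (SE 0.152). The files pair none of these with a gene.

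Below the top rises, sanpodo (spdo), which encodes a transmembrane protein of Notch signalling, rose by 3.05 on the log2 scale (SE 0.139). CG7387 was not well above background on any control_23C array and was at least 2.64-fold higher in activated_31C (adjusted p = 5.76e-05). Its controls' mean was −8.86 against −6.13 in activated_31C. The gene tun rose by 1.49, CG4681 by 1.44, CG11825 by 1.35 and meigo by 1.26 on the log2 scale. The RNA lncRNA:CR32194 rose by 1.22 (SE 0.0847), and COX5BL, named for cytochrome c oxidase subunit 5B, rose by 1.17 (SE 0.198). CG4681 was well above background on 3 of the 4 control_23C arrays. In the Release 6 gene table spdo overlaps PH4alphaEFB, CG7387 overlaps MED24, mbf1 overlaps nxf2, tun overlaps Zasp52, CG11825 overlaps CG33474, lncRNA:CR32194 overlaps CG34253 and COX5BL overlaps Trmt6, so these rises are uncertain as to their gene. With normexp background correction the log2 differences shrank to 0.61 for CG7387, under the bound above, 0.72 for CG4681 and 0.68 for COX5BL, which missed the threshold. Those of tun (0.77) and lncRNA:CR32194 (0.71) shrank as well but passed. The offset added in that correction shrinks dim differences by itself, so the smaller values do not show a background effect.

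Among the falls, CG7720 was lower by −1.10 on the log2 scale (SE 0.136, adjusted p = 0.000451). The log2 difference was −0.84 for CG43051, −0.79 for CG33941, −0.74 for CG41284, −0.73 for CG42458 and −0.71 for CR31032. DMAP1, which encodes a subunit of chromatin-modifying complexes, fell by 0.70 on the log2 scale (SE 0.0400, adjusted p = 1.07e-05). Saf6, which encodes a TAF-like factor, fell by 0.70 (SE 0.0509), and the chromatin protein gene mod(mdg4) fell by 0.60 (SE 0.0547). Wdr24, which acts in the nutrient-sensing GATOR2 complex, differed by −0.70 (SE 0.109) and was well above background on 3 of the 4 activated_31C arrays. The gene atos fell by 0.67 on the log2 scale (SE 0.108). Saf6 overlaps Dbp21E2 in the Release 6 gene table, CG33941 overlaps Asator, CG43051 overlaps bun, CG42458 overlaps Rac2 and mod(mdg4) overlaps 6 pre-mod(mdg4) genes, so these falls are uncertain as to their gene. With normexp background correction, whose offset by itself shrinks dim differences, CG41284 (−0.51), CG42458 (−0.52) and Wdr24 (−0.43) missed the threshold. CG41284 (−0.68) and CG43051 (−0.95) missed it with those 3 arrays left out, at about the size reported but with fewer arrays.

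**Figure D2:**
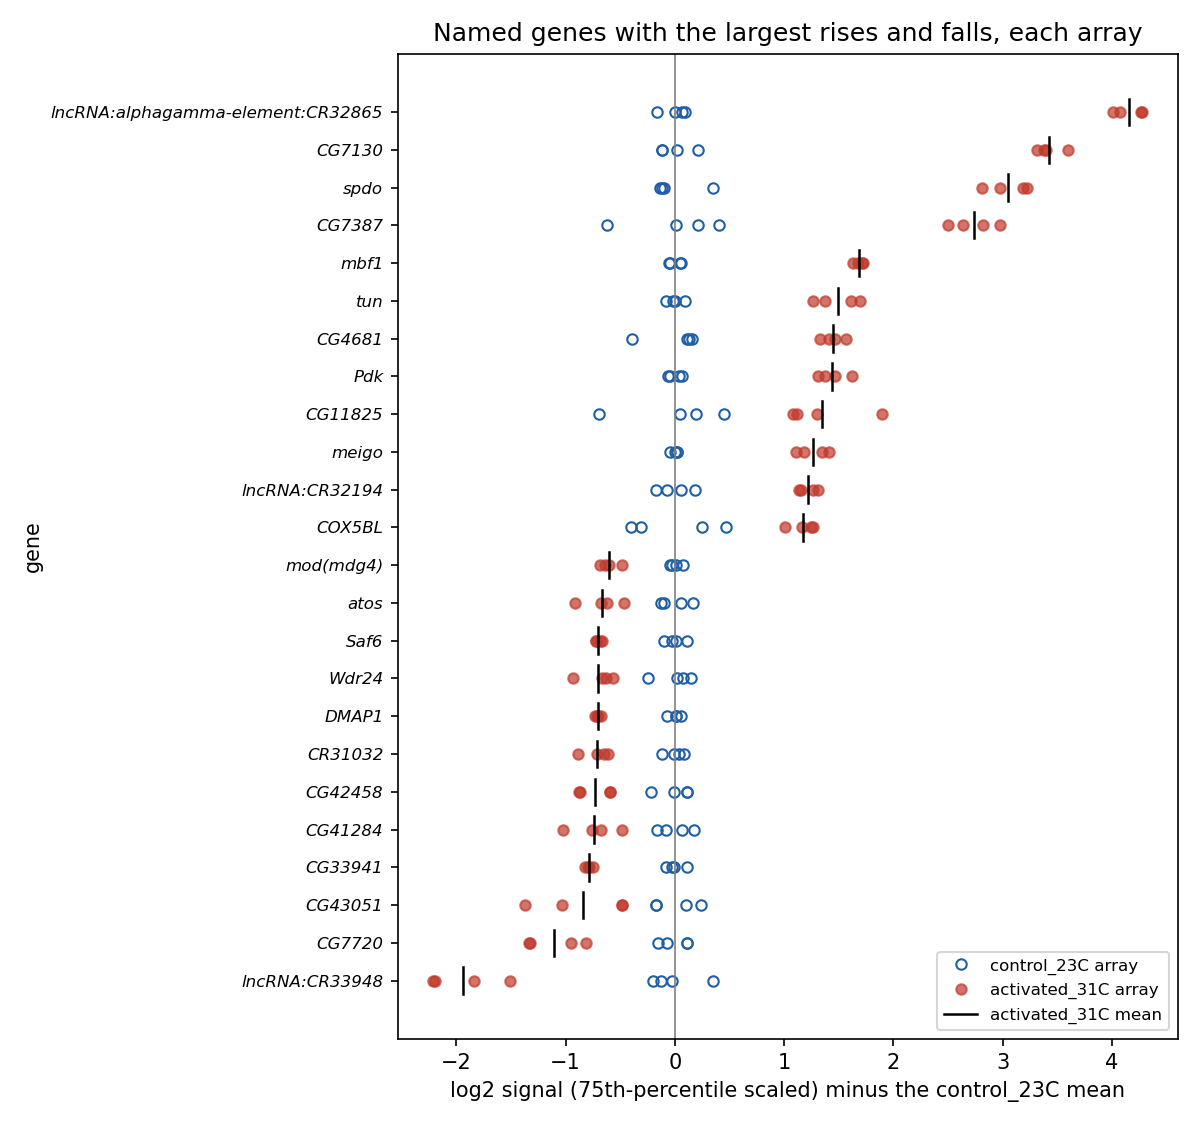
Log2 signal on each array minus the control_23C mean for the 12 largest rises and the 12 largest falls among genes with a symbol. Open circles are control_23C arrays, filled circles activated_31C arrays and bars the activated_31C means. The groups do not overlap for any of these genes, as the rule for choosing them required, and the rises reach 4.16 against −1.94 for the largest fall. The controls of CG7387 were not well above background.

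Gene lists fixed before the data were examined could be read only in small part, since 16 of their 546 entries had a named probe that was tested. Over all units 44.4% passed the threshold, with a median absolute change of 0.41 among them. A single member that passes therefore gives no result about its list. Of 25 heat-inducible genes and co-chaperones, 2 were measured and both rose. Both also passed adjusted over the list alone, which had to follow from the adjustment over all units and adds no support. Besides CG7130, lncRNA:Hsromega, a nuclear RNA known for its induction by heat, rose by 0.77 on the log2 scale (SE 0.0531, adjusted p = 2.80e-05). All 4 of its tested probes differed in the same direction. It overlaps mir-4951 in the Release 6 gene table, so the rise is uncertain as to its gene. Of 24 activity-regulated candidates 1 was measured, and CrebA, which encodes a transcription factor of the secretory pathway, rose by 0.42 (SE 0.0927, adjusted p = 0.00781). Its log2 difference was 0.22 (SE 0.124) and missed the threshold after centring on spike-in controls.

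The glycolytic enzyme gene Ald1 rose by 0.68 on the log2 scale (SE 0.0765, adjusted p = 0.000271), as the 1 measured member of 14. It overlaps asRNA:CR44321 in the Release 6 gene table, so the rise is uncertain as to its gene. Smaller rises were those of Hsc70-1 among the constitutive chaperones, by 0.27 (SE 0.0843, adjusted p = 0.0329), and of chrb among the stress genes of JNK and JAK/STAT signalling, by 0.24 (SE 0.0518). Sod1, which encodes a superoxide dismutase, rose by 0.21 (SE 0.0431) from the detoxification list. Of these, Hsc70-1, chrb and Sod1 rose by less than the median absolute change of 0.41 among all units past the threshold. The same genes missed the threshold after quantile normalization, where the difference of Sod1 turned to −0.0356. They missed it after spike-in centring as well. Without control_23C replicates 3 and 4 both Sod1 (0.20) and Hsc70-1 (0.33) missed it. Sod1 (0.21) also did with activated_31C replicate 3 left out besides. These differences were about as large as reported or larger, but with fewer arrays. Hsc70-1 missed it with array weights and with no filter, and without control_23C replicate 1, 2 or 3 or activated_31C replicate 2 or 4 (0.23 to 0.26). For each of these 4 lists the 1 measured member also passed over the list alone. With 1 member that is the unadjusted p, so it adds no support. The Egfr inhibitor gene kek1, from the ERK feedback list, differed by 0.03 (SE 0.0671, adjusted p = 0.744).

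Of 29 neuronal markers 2 were measured, both potassium channel genes. Shaker (Sh) fell by 0.16 on the log2 scale (SE 0.0521, adjusted p = 0.0382), a call that was lost without control_23C replicate 1, 2 or 3 or activated_31C replicate 1, 3 or 4, where the difference was −0.17 to −0.13. It was also lost after median centring (−0.12), after spike-in centring (−0.36, SE 0.141), with no filter (−0.16) and with both sets of several arrays left out (−0.16 and −0.17). With no filter or fewer arrays the fall thus kept about its size. Sh overlaps CG12672, CG6867 and CG15373 in the Release 6 gene table, so that fall is uncertain as to its gene. The channel gene slo differed by −0.0982 (adjusted p = 0.206), and 1 of the 2 passed adjusted over the list alone. The male-specific RNAs of dosage compensation did not pass. The difference was 0.61 for lncRNA:roX2 (SE 0.314, adjusted p = 0.154), whose 2 probes differed in sign, and 0.32 for lncRNA:roX1 (SE 0.306, adjusted p = 0.440).

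Ribosomal protein genes were the 1 list with enough measured members for a list test. None of the 4 measured genes (sta, RpL7, RpL11 and RpL29) passed the threshold, and 0 passed adjusted over the list alone. The probe of RpL7 read a control_23C mean of −3.52, against 6.11 for sta, 5.37 for RpL11 and 5.67 for RpL29. The largest difference was that of RpL11, at 0.34 (SE 0.244, adjusted p = 0.297), which dropped to 0.10 without control_23C replicate 1. Their mean difference was 0.19 and their median 0.15 on the log2 scale (camera p = 0.222 with a preset correlation), and p = 0.466 with an estimated correlation. The mean was −0.00703 after quantile normalization and −0.0175 after spike-in centring. The other 14 lists, which include glia, photoreceptors, fat body, muscle, gut, the circadian clock and immune genes, had 0 measured members and give no result here.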

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

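The tests of background, brightness, scaling, roX1 level, slide, heat and tissue markers were chosen only after the results were seen, although the scalings they use had been chosen earlier, while what to look for in the other splits of the arrays and the other probes of a target was written before those tests were run.

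In 5 of the 74 groups of 4 arrays checked, a single array lay far from the other 3 for its gap over the whole range, against 3.7 that chance gives at 1 in 20. The ratio was 0.923 for spdo in control_23C, where replicate 4 was highest at −3.71. It was 0.919 for CG4681 in control_23C, with replicate 1 lowest at −6.77, and 0.863 for CrebA in activated_31C, with replicate 1 highest at −1.26. It was 0.973 for RpL11 in control_23C, with replicate 1 lowest at 4.65, and 0.832 for Hsc70-1 in control_23C, with replicate 4 highest at 1.24.

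The first pattern was the difference between the groups itself. Of the 35 splits of the 8 arrays into 4 and 4, only the real 1 gave as many targets on either side (3494 higher and 4453 lower) or as many changed at least 2-fold (908). The highest other split gave 10 targets on its larger side, 0 on its smaller side and 10 changed at least 2-fold, which argues against a chance split, although 35 splits allow no finer measure. Each other split mixes the groups, so their difference enters the spread within its sides and lowers its counts. The size of the contrast is thus no measure of the effect, and a slide difference would give it as well. An additive background difference between the slides would leave few calls among bright targets, but 36.1% of the 25% brightest targets passed the threshold against 41.2% of the 25% dimmest. Changes of at least 2-fold lay mostly among dim targets, with 476 in the dimmest 25% and 126 in the brightest. Normexp background correction called 527 of that size, so a part of background in the larger changes is left open. A smooth brightness-dependent difference between the slides is removed by quantile normalization, after which 802 of the 908 targets were still called at 2-fold or more. That covers the larger changes only. Over all calls the counts moved to 2774 higher and 5424 lower, so such a difference is left open for the smaller changes. A probe-by-probe difference between the slides cannot be told apart from the groups, with 0 slides that held both, nor can heat itself from neural activity, with 0 samples kept at 31 °C without the channel.

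The second pattern was a set of 198 targets whose signal on control_23C replicate 3 lay over 4 log2 units below their median of the 8 arrays. Of these, 194 were also lower by over 2 log2 units on control_23C replicate 4 and 134 on activated_31C replicate 3, and 3 were past the threshold between the groups. On control_23C replicate 3, 59 of the 198 were well above background, so the size of the fall is uncertain for the rest. A local defect of the array would spare other probes of the same target, but in 100% of the 30 targets with several probes all others were lower too. A pool without males would lack the male-specific roX1, whose level there was 0.46 above the median of the other controls. A tissue missing from that pool may account for it and cannot be told apart, since 0 members of the tissue marker lists were measured.

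The third pattern was the excess of lower over higher targets, which held in the middle of the brightness range only. By brightness in 4 equal parts, from the dimmest up, 992, 787, 751 and 964 targets were higher against 854, 1463, 1484 and 652 lower. The share was 48.8% without control_23C replicates 3 and 4 and 49.1% without these and activated_31C replicate 3. Whether the scaling of the arrays made it cannot be told apart. The higher share was 44.0% as reported, 33.8% after quantile normalization, 22.8% after spike-in centring and 51.9% when each array was centred on the median of its probes well above background. That last scaling largely sets the balance of higher and lower targets itself, but so does the reported one. The median difference over all targets was −0.00716 as reported and 0.034 with median centring. A turned majority was the outcome set for a scaling cause, but median centring was left out when that rule was read. The question therefore stays open.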

How the results depend on the processing

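Alternatives to the reported settings were fixed before the data were examined, except normexp on the median spot signal and leaving out several arrays that stood apart. The counts kept within 1.5 times of the reported ones except as follows, and the cause was not tested unless given. Spike-in centring lowered all log2 differences by the same 0.204 and called 1218 higher targets. It also raised SEs, that of Sod1 from 0.0431 to 0.131, and called fewer lower targets (4122) despite the downward shift. The shift rests on 7 spike-ins, whose levels differed between the groups at p = 0.114 by an exact permutation test. Normexp called 527 changed at least 2-fold. A threshold of 1.5-fold gave 2357 and limma's treat against 1.2-fold gave 2951, as lower size limits do. Without control_23C replicates 3 and 4 and activated_31C replicate 3, with fewer samples, 2203 targets were higher and 2283 lower. Leaving out a single array gave 2992 to 3265 higher, 3756 to 4371 lower and 879 to 924 changed at least 2-fold. With the replicate number as a block, 3166 were higher, 3975 lower and 899 changed at least 2-fold. The numbers were not taken as pairing the samples, since same-numbered deviations correlated over targets at 0.20, 0.0714, 0.65 and −0.284, and only number 3 matched itself best. The 34 genes chosen by the rule had 745 alternative values. In 35 a call was lost in the same direction, and in 1 it was lost with a turn, Sod1 at −0.0356 after quantile normalization. The other 709 stayed called or uncalled as reported, though uncalled values also changed sign: kek1 after quantile normalization (−0.0736), after spike-in centring (−0.173) and without activated_31C replicate 2 (−0.00425), and lncRNA:roX2 with the mean of its probes (−0.0298). The ribosomal list passed no threshold, with means from −0.0175 to 0.258. The slide as a block and the probes of TrpA1 and elav could not be run. Signal over background limits dim targets, of which 84 were below it on every array of a group.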

Other observations

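These groups were chosen after their values were seen. Of 5 spliceosomal snRNA genes tested, 3 rose. The log2 difference was 0.47 for snRNA:U11 (SE 0.0964, limma adjusted p = 0.00565), 0.40 for snRNA:U2:34ABb (SE 0.0881) and 0.22 for snRNA:U1:21D (SE 0.0614), with all 4 activated_31C arrays above all controls in each. After spike-in centring, which lowers all differences by 0.204, these were 0.26, 0.20 and 0.02 and none passed. That centring also raised their SEs, to 0.128, 0.151 and 0.148. After quantile normalization snRNA:U1:21D (0.12) did not pass. Of 5 snoRNA genes 0 passed the threshold at an adjusted p under 0.05 with limma, and 0 at an unadjusted p under 0.05. Among 14 long non-coding RNA genes 4 rose and 2 fell, a share of 42.9% that is near the 44.4% over all units. Of these genes, lncRNA:CR33963 rose by 1.01 on the log2 scale (SE 0.145).

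Single genes outside the fixed lists changed in both directions. Mob2 rose by 0.94 (SE 0.0451, adjusted p = 4.93e-06), and Pka-R2, a regulatory subunit of protein kinase A, rose by 0.45 (SE 0.0410). The cation channel gene Trpm rose by 0.64 (SE 0.0694) and the ATP synthase gene ATPsynbeta by 0.59 (SE 0.0563). The ATPsynbeta probe read a mean of −0.457 in control_23C, and other probes of the gene may be unnamed. Gbeta5 fell by 0.35 (SE 0.0606), PlexA by 0.25 (SE 0.0495) and Sdhaf3 by 0.23 (SE 0.0578). After spike-in centring Pka-R2 (0.25, SE 0.132) and ATPsynbeta (0.38, SE 0.140) missed the threshold, while the others here passed in the same direction. The mitochondrial ribosomal protein gene mRpL52 fell by 0.43 on the log2 scale (SE 0.0557) and passed after quantile, median and spike-in scaling as well. mRpL40 differed by −0.12 (SE 0.0413) and mRpS33 by 0.15 (SE 0.0527), both close to the threshold. After spike-in centring both missed it, with mRpL40 at −0.325 and mRpS33 turned to −0.0505. The call of mRpL40 was also lost after median centring (−0.0799), and that of mRpS33 after quantile normalization (0.135). Other mitochondrial genes looked at did not pass as reported: mRpL14 (−0.0657), COX4 (0.108), COX5A (0.189), ND-23 (0.0389), ND-B14.7 (−0.0109) and ND-B17.2 (−0.0140). Of these, ND-B14.7 (−0.246) and ND-B17.2 (−0.224) passed as falls after quantile normalization only.

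Several named genes varied widely between arrays of the same group. CG9672 read −6.97 on control_23C replicate 3, −4.39 on replicate 4 and −3.49 on activated_31C replicate 3, and between 0.54 and 1.46 on the other arrays. CG6484 was likewise between −3.05 and −2.68 on those arrays and between 0.17 and 1.32 elsewhere. Cyp4g1, known for its part in making cuticular hydrocarbons, read 1.95 on activated_31C replicate 4 and between −7.58 and −3.43 on the other arrays. Its difference between the groups was 3.52 (SE 1.72) and did not pass the threshold (adjusted p = 0.138). Cyp4g1 was well above background on 1 of the 4 control_23C arrays and on 4 activated_31C arrays. Its low control readings and the size of its difference are therefore uncertain.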
